A study of Oryza sativa with 7 samples.

How the data were processed

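The material was shoots of rice seedlings aged 14 days, from which biotin-labelled cRNA was made from 6 ug of total RNA and hybridised to Affymetrix arrays, per the labels' protocols. Each of the 7 samples had 1 array. The values used were the deposited intensity values, 1 per probe set and array, for 57381 probe sets. They were made with MAS5, per the submitters' processing notes. The version, the scaling target and any later step are not given in the sources used here. The values were linear, from 1 to 13776.48, and the array medians differed little, so they were taken as already scaled and not normalized again. Array depth has no count, and the number of arrays limits the precision.

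Groups came from the genotype labels: the OsSIK2 mutant (1 array), full-length overexpression (2 lines), truncated overexpression (2 lines), the TP309 control of the overexpression lines (1) and the Nip control of the mutant (1). The labels name no control for the truncated lines and do not say which part was removed. The labels call every array a first biological replicate of its own line, so lines served as replicates and were numbered in accession order, and p-values measure the spread between independent lines on single arrays. No batch is labelled.

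Probe sets were named through the platform annotation and a gene table of the assembly ASM3414082v1, which was used for names only. A single gene was given for 22436 probe sets, several for 95 and none for 34850. The annotation covered 17905 genes, of which 2457 have a name other than a locus number (3192 probe sets). Genes without such a name are printed as locus identifiers, and no function is given for them. No probe set carried the name or locus of OsSIK2 in these tables, so its signal is not analysed here.

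Values were transformed to log2(value + 21), where 21 is the 20th percentile of all values. Fold changes on this scale understate those of dim probe sets. The 123 control probe sets were left out, and of the others those with a mean log2 value above the median were kept, 28629 probe sets. A linear model with 3 groups (5 arrays, 2 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step (prior degrees of freedom 3.96, median posterior standard deviation 0.115). Tests were two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and an adjusted p threshold of 0.05. The lone TP309 array was assumed to vary like the lines. Beside the tests, probe sets at least 2-fold apart from the control in both lines were counted. The mutant and Nip, 1 array each, were compared by fold alone. Overlaps and correlations between comparisons that share TP309 were set beside 100 simulations of unchanged lines, drawn with each probe set's posterior spread. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

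Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, over 14953 genes (the brightest probe set of each). For the mutant, the percentile of each list's median among 10000 random lists matched on mean expression was taken. Before the data were examined, 27 lists had been written as patterns of protein descriptions. The annotation holds mostly symbols, and 18 of the 27 patterns matched under 5 genes, so 39 lists of symbols were written after the annotation was seen and before any comparison was made, and of these 38 had at least 5 kept genes. The 8 of the earlier lists that could be tested are reported beside them. Of these earlier lists, those not described in the report (DREB/CBF, jasmonate, NAC and WRKY) had camera adjusted p-values of 0.147 or more in each comparison. Some symbols were matched too widely and left in place, since the comparisons had been seen by then. The pathogenesis-related pattern also took lipid genes named OPR. It took NH1, NH2, APR-like1, ASPR1 and ASPR2 as well, through other names such as NPR1, APR1 and TPR1. Of its kept genes, only CH16, chia4a and a gene named chitinase are chitinases, and these are also on the chitinase list. The gibberellin list also took CYP701A8, immune signalling took an actin gene, root markers took Lsi6 and the floral list took MADS-box genes that act outside flowers.

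The rule for named genes was written before the data were examined. It takes, per tested comparison, named genes past the threshold, filled up from named genes at least 2-fold apart in both lines when fewer than 20 pass, and for the mutant the 12 largest differences each way. Genes outside the rule are named where a count was 5 or less or where they were singled out after their values were seen, as the text says.

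The steps were tested on simulated data with the real arrays' means. For full-length lines against TP309, with spreads drawn from the fitted distribution, 39 of 100 probe sets changed 2-fold and 97 of 100 changed 4-fold were recovered over 28629 probe sets, and 4.2% of the calls were false. With each probe set's posterior spread, 89 and 100 were recovered and 16.4% of the calls were false, so adjusted p-values may be too small by that measure. For truncated against full-length lines, 67 and 98 were recovered with 4.6% false calls, and 97 and 100 with 6.6%. Of 1000 lists of 20 unchanged genes, 3.5% had a camera p under 0.05 at the preset correlation and 0% with an estimated one, and 100 of 100 lists moved by 0.5 were found both ways. The simulated genes were drawn independently, so this does not show that the preset correlation is sound for lists whose genes vary together. The chitinase and PBZ1 list, for example, had an estimated correlation of 0.756. Alternatives covered the normalization, the pseudocount, the filter on dim probe sets, the intensity trend, the samples in the fit, the control arrays, the fold threshold, the list correlation and leaving out each line. Their larger effects are given in the closing section, where smaller changes of a count are mostly left out.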

Results

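Transcript levels were measured in shoots of rice seedlings at an age of 14 days on 7 Affymetrix rice arrays, to find genes regulated by OsSIK2, a receptor-like kinase gene. The arrays covered a sik2 mutant (1 array), 2 lines overexpressing the full-length gene (1 array each), 2 lines overexpressing a truncated gene (1 array each) and 2 unaltered controls. The controls were the japonica cultivars TP309, labelled as the control of the overexpression lines, and Nipponbare (Nip), labelled as the control of the mutant. No control was labelled for the truncated lines, and TP309 was used for them. Each array gave a MAS5 signal for 57381 probe sets. Median signals were 60.7 in sik2, 56.8 and 60.7 in the full-length lines, 56.7 and 56.6 in the truncated lines, 57.4 in TP309 and 63.5 in Nip. Every genotype or line was measured on 1 array, so the number of arrays limits the precision of every value, and the comparison of sik2 with Nip has no replicates.

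Across the 28629 probe sets kept, log2 signals of sik2 and Nip had a correlation of 0.989, and those of TP309 and the 4 overexpression lines had correlations of 0.977 to 0.992. Between these 2 sets of arrays the correlations were 0.965 to 0.979. The standard deviation of the log2 differences was 0.237 between the 2 full-length lines, 0.252 between the 2 truncated lines, 0.236 between sik2 and Nip and 0.353 between TP309 and Nip. At least 2-fold apart were 112 probe sets between the full-length lines, 187 between the truncated lines and 323 between the cultivars. RNA quality was read from the control probe sets. The 3-prime over 5-prime ratio of actin was 8.51 in sik2, 11.23 and 9.95 in the full-length lines, 9.85 and 10.34 in the truncated lines, 10.39 in TP309 and 6.75 in Nip. The ratio of GAPDH was 2.97 in sik2, 2.7 and 2.77 in the full-length lines, 3.31 and 2.99 in the truncated lines, 2.91 in TP309 and 3.67 in Nip. Clock genes, read as a check of the time of harvest, differed from the own control by a median absolute log2 value of 0.07 to 0.15 per array. Of 11 seed storage genes 4 were kept, among them GLB at 830.7 to 1092.3 and GLUA-2 at 630.1 to 798.1 over the 7 arrays. The signal of OsSIK2 itself was not analysed here, because the annotation used here gave no probe set that name, so the overexpression and the mutation were not checked against the labels.

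Which genes differ when full-length OsSIK2 is overexpressed was asked by comparing the 2 full-length lines with TP309. LOC4340325 rose from a signal of 19.2 in TP309, to 730.9 and 791.9 in the lines, a log2 change of 4.28 ± 0.19 (SE, 2 lines against 1 array; limma adjusted p = 0.0165). The TP309 signal is under the pseudocount of 21, so the size of this change depends on it. LOC4331398 rose at both of its probe sets, by 2.08 ± 0.13 and 2.12 ± 0.14 on the log2 scale (limma adjusted p = 0.0326 for each), from 448.8 and 351.8 in TP309 to 1929.4 to 2013.2 and 1541.1 to 1660.8. LOC4330535 fell by 3.04 ± 0.16 on the log2 scale (limma adjusted p = 0.0178), from 2420.1 in TP309 to 271.1 and 280.9, and the truncated lines, sik2 and Nip stood at 255.4, 313.1, 321.9 and 321. These 4 probe sets (3 higher and 1 lower, in 3 genes) were all that passed the test, and 920 had an unadjusted p under 0.05. The 3 genes were chosen for naming after their values were seen. All 4 probe sets also passed in the truncated lines with the same sign, so none was particular to the full-length lines. The 3 higher ones were also higher in sik2 than in Nip, by log2 differences of 4.13, 5.15 and 5.86. LOC4330535 was high in the single TP309 array only. Without either full-length line no probe set passed (1654 and 808 at an unadjusted p under 0.05), whereas 315 passed without truncated line 1 (216 higher, 99 lower) and 323 without line 2 (221 higher, 102 lower). With Nip as a second control array 1 passed, and with only the 2 groups compared in the fit 322 passed.

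Among genes with a name, 6 differed from TP309 by at least 2-fold in both full-length lines, and none passed the test. Higher were CYP71Z7, a cytochrome P450 of phytocassane synthesis, with log2 differences of 3.51 and 1.41 in lines 1 and 2, and PBZ1, a probenazole-inducible pathogenesis-related protein, with 2.12 and 1.15. The lipoxygenase gene CM-LOX1 had 1.53 and 1.01, and the peroxiredoxin gene R1C-Prx had 1.19 and 1.3 (mean 1.25 ± 0.13 SE, limma adjusted p = 0.258). The gene recorded as HSF6 (HSFA2C), a heat stress factor, was 2.65-fold higher (log2 1.41 ± 0.15 SE, limma adjusted p = 0.258), at 634.3 and 612 against 222.2. Its annotation record also carries ARD1 and OsIDI1, names of an unrelated enzyme, acireductone dioxygenase, so which transcript was measured is uncertain. DL, a YABBY transcription factor needed for the leaf midrib, was 2.44-fold lower (log2 −1.29 ± 0.18 SE, limma adjusted p = 0.535), at 79.9 and 102 against 251.1. TP309 itself was below Nip for CYP71Z7 (62.5 against 131.8), PBZ1 (1080.4 against 1980) and CM-LOX1 (179.3 against 414.2), and above it for DL (141.8 in Nip). It was near Nip for R1C-Prx (39.7 against 42.5) and above it for the HSF6 probe set (85 in Nip). With 1 TP309 array, its own deviation and an effect of the construct cannot be told apart. In all, 48 probe sets were at least 2-fold apart from TP309 in both lines, 45 higher and 3 lower. In 100 simulations of unchanged lines against the same control, with each probe set's posterior spread, the means were 6.56 higher and 6.99 lower. In the test on simulated data, 23 unchanged probe sets met this rule with spreads drawn from the fitted distribution, and 10 with the posterior spread. Taken in 1 line only, 135 and 129 probe sets were 2-fold apart without line 1 or 2, and 225 were in both lines with Nip in place of TP309.

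As a group, chitinases and PBZ1 were higher in the full-length lines than in TP309, with 11 of 11 genes above 0 and a median log2 change of 0.26 (0.33 in line 1 and 0.24 in line 2; camera adjusted p = 8.14e-06; adjusted p = 0.92 with an estimated correlation). No member passed over all probe sets, and 3 passed adjusted over the list alone. CH16 differed by 0.67 and 0.84 in the 2 lines and CH6 by 0.71 and 0.74. Genes of diterpenoid phytoalexin synthesis were higher at 6 of 9 members, with a median of 0.29 (camera adjusted p = 0.016; adjusted p = 0.92 with an estimated correlation), led by CYP71Z7 at 2.46, CYP701A8 at 1.88 and CYP99A3 at 0.85. CYP701A8 stood at 637.5 in line 1 and 79 in line 2. Small heat shock protein genes were lower at 12 of 14 members, with a median of −0.18 (camera adjusted p = 0.00985; adjusted p = 0.92 with an estimated correlation), among them HSP17.9A at −0.61. Chlorophyll synthesis genes were higher at 15 of 18 members, with a median of 0.12 (camera adjusted p = 0.0396; adjusted p = 0.92 with an estimated correlation). UPD2 stood at 0.21 and ALADH at 0.17, and PORA at −0.34. No member of these last 3 groups passed the test over all probe sets or adjusted over the list alone. Of the lists written before the annotation was seen, heat shock proteins were lower at 16 of 18 genes (median −0.16, camera adjusted p = 0.00247; adjusted p = 0.478 with an estimated correlation). In that set, 5 diterpenoid genes, 3 of them higher, had a median of 0.29 (camera adjusted p = 0.0409; adjusted p = 0.688 with an estimated correlation).

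In the 2 truncated lines, compared with TP309, LOC4340325 rose to signals of 751.7 and 1003.5 against 19.2 (log2 4.47 ± 0.19, a size that again depends on the pseudocount of 21; limma adjusted p = 0.011). LOC4331398 rose at both probe sets, by 1.94 ± 0.13 and 2.01 ± 0.14 on the log2 scale (limma adjusted p = 0.0155 and 0.0161). LOC4331137 fell by 3.12 ± 0.16 (limma adjusted p = 0.011), from 972.3 to 82.6 and 104.4, and the full-length lines stood at 1027 and 1070.8. Also lower were LOC4330535 (−3.01), LOC4348119 at 2 probe sets (−2.67 and −2.65), LOC4327106 at 3 probe sets (−2.51, −2.46 and −2.26), LOC4343628 (−1.9) and LOC4337104 (−1.63), with limma adjusted p-values of 0.011 to 0.0418. A probe set with no gene in the annotation rose by 3.43 ± 0.25 (limma adjusted p = 0.0232), from 117.4 to 1480.9 and 1454.2. In all, 13 probe sets passed the test, 4 higher and 9 lower, in 8 genes and 1 probe set without a gene, and 854 had an unadjusted p under 0.05. These genes, too, were singled out after their values were seen. Without full-length line 1 or 2 none passed (909 and 928 at an unadjusted p under 0.05), whereas 849 passed without truncated line 1 (262 higher, 587 lower) and 294 without line 2 (170 higher, 124 lower). With only the 2 groups compared in the fit none passed (925 at an unadjusted p under 0.05), and 6 passed with Nip as a second control array.

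None of the 7 named genes at least 2-fold from TP309 in both truncated lines passed the test. The HSF6 probe set, uncertain as above, was 2.52-fold higher (log2 1.33 ± 0.15 SE, limma adjusted p = 0.171), the expansin gene EXP1 (EXPA1) had log2 differences of 1.01 and 1.35 in lines 1 and 2, and CRSH2, a calcium-dependent enzyme of ppGpp synthesis, had 1.47 and 1.5. CRSH2 also stood at 0.38 and 2.37 in the 2 full-length lines, so its mean change of 1.48 had an SE of 0.72. Lower were the mini zinc finger gene MIF3 (−1.28 and −1.79), DL (−1.53 and −1.32), TDL1B, coding for a small secreted protein (−1.17 and −1.2; limma adjusted p = 0.122), and the expansin gene EXP7 (EXPA7; −1.23 and −1.09; limma adjusted p = 0.28). In all, 65 probe sets were at least 2-fold apart from TP309 in both lines, 24 higher and 41 lower. Unchanged lines simulated with the posterior spread gave means of 6.85 higher and 6.74 lower. Taken in 1 line only, 257 probe sets were 2-fold apart without line 1 (79 higher, 178 lower) and 126 without line 2 (74 higher, 52 lower), so the balance of higher and lower turned, and 287 were in both lines with Nip in place of TP309.

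Chitinases and PBZ1 were higher in the truncated lines as well, with 11 of 11 genes above 0 and a median log2 change of 0.51 (camera adjusted p = 3.49e-11; adjusted p = 0.819 with an estimated correlation). The median was 0.28 in line 1 and 0.74 in line 2, so its size depends on the line. Adjusted over the list alone 4 members passed, and over all probe sets none did. Cht4 differed by 0.83 and 1.28 in the 2 lines, CH16 by 0.65 and 0.97, and PBZ1 by −0.02 and 0.82. The median log2 difference of TP309 from Nip over this list was −0.22. Late embryogenesis abundant (LEA) proteins and dehydrins, which protect cells during drying, were higher at 7 of 8 genes, with a median of 0.4 (camera adjusted p = 0.0145; adjusted p = 0.819 with an estimated correlation). PM1 stood at 0.75, RAB21 at 0.53 and RAB16B at 0.51, and no member passed the test, also adjusted over the list alone. RAB16B also differed between the 2 full-length lines, at −0.54 and 0.89 over TP309. Of the lists written before the annotation was seen, LEA proteins were higher at 5 of 6 genes (median 0.4, camera adjusted p = 0.0211; adjusted p = 0.768 with an estimated correlation). The pathogenesis-related pattern of that set was higher at 7 of 10 genes (median 0.06, camera adjusted p = 0.0211, and 0.768 with an estimated correlation), and 2 passed adjusted over the list alone. Most of its kept genes were matched too widely, so it is no measure of pathogenesis-related genes.

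**Figure D1:**
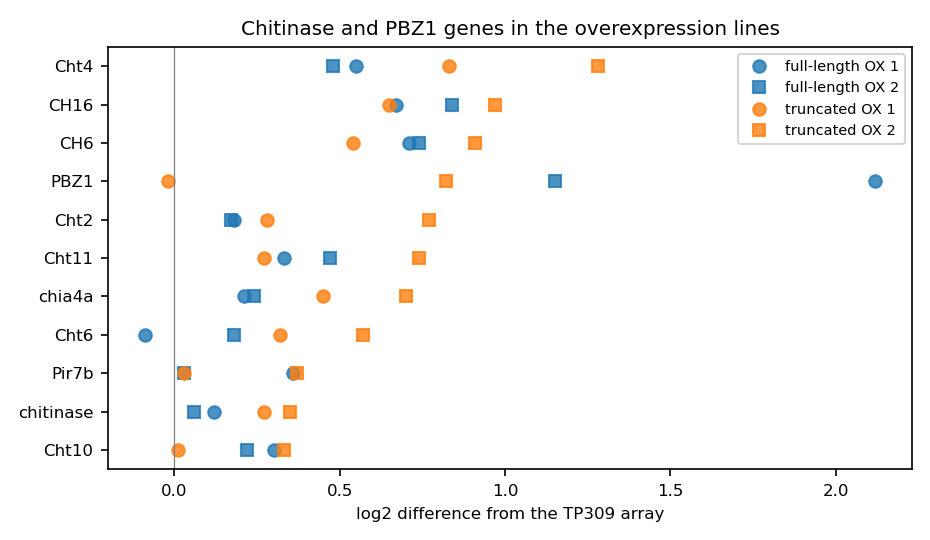
Log2 difference from the TP309 array (horizontal axis) of the 11 chitinase and PBZ1 genes (vertical axis) in each full-length and truncated line, 1 point per line. PBZ1 spans −0.02 to 2.12, and CH16 lies between 0.65 and 0.97 in all 4 lines.

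Both kinds of line share the single TP309 array, so part of any overlap may come from that array, which could not be split. Of the probe sets 2-fold apart from TP309, 12 were higher in both kinds of line (0.038 for independent lists; 2.02 on average and at most 6 in simulations of unchanged lines against the same control). Lower in both kinds were 2 (0.004 for independent lists; 2.05 on average and at most 6 in simulations). Over all kept probe sets the log2 changes of the 2 comparisons had a correlation of 0.37 across probe sets, which are not independent replicates, against 0.67 in simulations. Their covariance was 0.0143 against 0.0191 in simulations, a difference of −0.00477. All these simulations used the posterior spread, under which fewer unchanged probe sets were 2-fold apart than with spreads drawn from the fitted distribution. Leaving out single lines gave overlaps of 18 to 22 probe sets in place of the 14 in both directions.

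The truncated and full-length lines were compared directly, a contrast that does not use the TP309 signal. Here 55 probe sets passed the test, 53 lower and 2 higher in the truncated lines, and 4 of the lower ones belong to named genes. EXP7, whose expansin loosens cell walls, fell by 1.68 ± 0.13 on the log2 scale (limma adjusted p = 0.0224), with signals of 135.9 and 151.8 in the truncated lines and 553 and 465 in the full-length lines. OsCel9E, an endoglucanase gene, fell by 1.35 ± 0.12 (limma adjusted p = 0.0322), from 285.7 and 250.7 to 96.8 and 87.8. TDL1B fell by 1.16 ± 0.1 (limma adjusted p = 0.0272), from 109.6 and 101.2 to 36.2 and 34.9. The transcription factor gene BZIP06 fell by 1.54 ± 0.16 (limma adjusted p = 0.0442), and this call was lost after quantile normalization (−1.49, adjusted p = 0.0714).

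Of the 55 probe sets, 8 have no gene in the annotation, and the rest belong to 42 genes. Those singled out after their values were seen include LOC4331137, which fell by 3.23 ± 0.13 (limma adjusted p = 0.0031), and LOC4348119, lower at 2 probe sets (−3.03 and −2.92). LOC4327106 was lower at 3 (−2.7, −2.58 and −2.33). LOC4351887 was lower at 2 (−4.36 ± 0.46 and −3.95 ± 0.38; limma adjusted p = 0.0442 and 0.0327). The first of its probe sets stood at 1557.6 and 1303.4 in the full-length lines, 20.6 and 98.7 in the truncated lines, 63.1 in TP309, 962 in sik2 and 2276 in Nip, and since 20.6 is under the pseudocount of 21, the size of its difference depends on it. The 2 higher were LOC4350979 (0.82, limma adjusted p = 0.0343) and a probe set without a gene (2.05, limma adjusted p = 0.0179). At 52 of the 53 lower probe sets the truncated mean lay below TP309, at 51 the full-length mean lay above it, and at 50 both held. The median log2 difference from TP309 was −1.05 in the truncated and 0.35 in the full-length lines, and 24 were at least 2-fold below TP309 in both truncated lines. At 50 both truncated lines were also below Nip, and the median log2 difference of sik2 from Nip was 0.07. At 46 of the 53 both truncated lines were below TP309, sik2 and Nip alike. The GAPDH ratio given above was higher in both truncated arrays than in both full-length arrays, and that of actin was not, while Nip had the highest GAPDH and the lowest actin ratio. Among clock genes, CCA1 stood at −0.51, PCL1 at 0.49 and PRR1 at 0.37 in truncated over full-length lines, and 3 of the 7 passed limma's test adjusted over the list alone. Beside the 55, 2150 probe sets had an unadjusted p under 0.05. Without full-length line 1 or 2 none passed (2873 and 1514 at an unadjusted p under 0.05), and with Nip in the fit 22 passed, all lower. Without truncated line 1 1775 passed (529 higher, 1246 lower) and without line 2 621 (254 higher, 367 lower), so the calls were then far less one-sided.

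**Figure D2:**
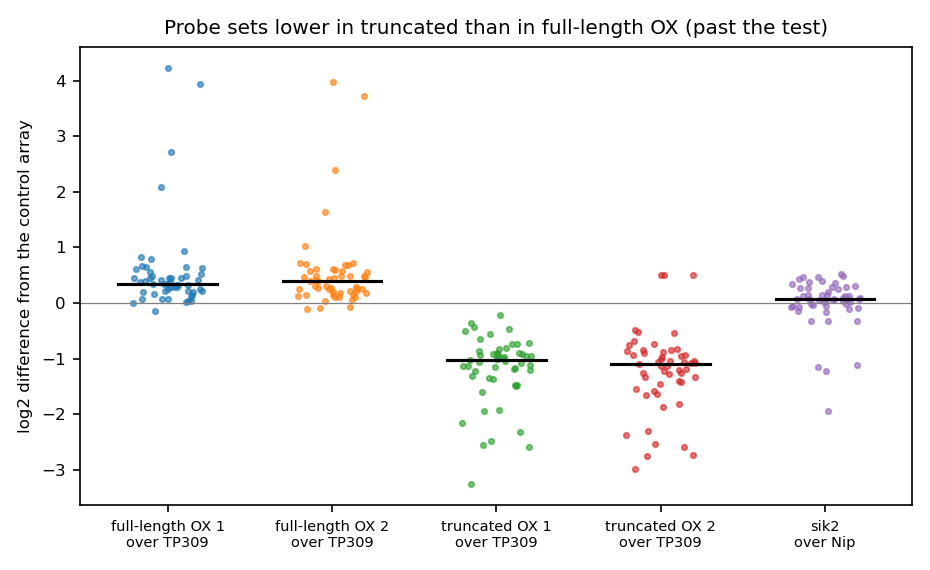
Log2 difference from the control array (vertical axis) of the 53 probe sets lower in truncated than in full-length lines, 1 point per probe set and array, for the 4 overexpression lines over TP309 and for sik2 over Nip. The median difference from TP309 is −1.05 in the truncated lines and 0.35 in the full-length lines, and the median of sik2 over Nip is 0.07.

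Among the gene lists, small heat shock protein genes were higher in truncated than in full-length lines at 14 of 14 members, with a median log2 difference of 0.2 (camera adjusted p = 0.00334; adjusted p = 0.89 with an estimated correlation). Against TP309 the median was 0.03 in the truncated lines (8 of 14 higher, camera adjusted p = 0.591) and −0.18 in the full-length lines. HSP22.3 stood at 1.13 and HSP18.6 at 0.49, and none passed the test. HSP22.3 had a signal of 614.4 in truncated line 1 and 164.8 in truncated line 2. Of the lists written before the annotation was seen, heat shock proteins were higher at 17 of 18 genes (median 0.18, camera adjusted p = 9.43e-04; adjusted p = 0.425 with an estimated correlation), with a median of 0.01 in truncated lines over TP309 (10 of 18 higher). Diterpenoid genes of that set were lower at 4 of 5 (median −0.24, camera adjusted p = 0.0484; adjusted p = 0.713 with an estimated correlation; −0.04 in truncated lines over TP309), and 1 passed adjusted over the list alone. The cell wall growth list did not pass as a whole (median −0.07, camera adjusted p = 0.369). EXP7 was its only member past the test over all probe sets, and 7 of its 28 members passed adjusted over the list alone. Its expansins went both ways, with EXP1 at 0.7, EXPB2 at 0.67 and EXP2 at 0.63 against EXP7 at −1.68 and EXP5 at −0.51.

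Of 38 gene lists tested in each comparison, the ones above were all that passed. No other list did. Among hormone lists, the median log2 changes in full-length and truncated lines were −0.06 and −0.01 for jasmonate, −0.01 and 0.07 for abscisic acid, −0.08 and 0.03 for ethylene, −0.02 and −0.01 for cytokinin, 0 and −0.04 for auxin and 0.13 and 0.05 for gibberellin. Among stress and defence lists they were 0.03 and 0.01 for immune signalling, −0.06 and −0.13 for germin-like proteins, 0.08 and 0.09 for DREB/CBF factors, −0.05 and 0.03 for WRKY factors, −0.1 and −0.09 for NAC factors, −0.02 and 0.06 for heat stress factors and large chaperones, 0.03 and 0.03 for ER folding, 0.01 and 0.03 for antioxidant enzymes and −0.04 and −0.01 for metallothioneins. Among metabolic lists they were 0.04 and 0.02 for photosynthesis, 0.08 and 0.07 for chlorophyll breakdown and senescence, 0.2 and 0.22 for secreted peroxidases and laccases, −0.03 and 0.01 for phenylpropanoids, 0.05 and 0.04 for sugar and starch and 0.09 and 0.03 for nitrogen. Among transport and signalling lists they were 0 and 0.05 for potassium and sodium transport, −0.02 and 0.06 for phosphate, −0.03 and 0.05 for iron and zinc, 0.06 and −0.05 for aquaporins and −0.02 and −0.02 for calcium-dependent kinases and sensors. Among growth lists and lists kept as checks they were 0.06 and −0.01 for cell wall growth, −0.04 and −0.07 for cell division, −0.1 and −0.02 for clock genes, 0.07 and 0.01 for root markers, −0.05 and 0.01 for MADS-box genes, −0.01 and −0.03 for cytosolic ribosomes and 0.01 and 0 for the proteasome. Of lists that passed in only 1 kind of line, apart from small heat shock proteins, the medians in the other were 0.11 for LEA proteins and dehydrins in the full-length lines, and 0.08 for diterpenoid and 0.03 for chlorophyll synthesis genes in the truncated lines. Over the lists that did not pass, the lowest camera adjusted p was 0.0907 in the full-length lines and 0.189 in the truncated lines. On the list of heat stress factors and chaperones, the HSF6 probe set, which may measure acireductone dioxygenase instead, was the 1 member past the test adjusted over the list alone in each kind of line. In truncated over full-length lines the lowest camera adjusted p after that of small heat shock proteins was 0.257. Beyond the counts given, adjusted over the list alone, 1 antioxidant gene passed in the full-length lines and 4 cell wall growth genes in the truncated lines. In truncated over full-length lines so did 4 diterpenoid genes, 2 germin-like genes, and 1 gene each among auxin, antioxidant, peroxidase and laccase, and sugar and starch genes. Median and mean log2 change had opposite signs for jasmonate, cytokinin, immune signalling, WRKY, ribosome, and heat stress factor and chaperone genes in the full-length lines. In the truncated lines they did so for cytokinin, immune signalling, WRKY, cell wall growth, chlorophyll synthesis, clock, metallothionein and root marker genes.

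The effect of the sik2 mutation was described from 1 mutant and 1 Nip array, with no test. JAZ2, a repressor of jasmonate signalling, had a signal of 891.8 in sik2 and 6.1 in Nip. The Nip signal is under the pseudocount of 21, so the size of the difference is set by it (log2 5.07, or 7.18 with no pseudocount) and no fold is given. The nicotianamine synthase genes NAS1 and NAS2, which make a metal chelator, were 3.01-fold and 2.75-fold higher, and the metal transporter gene Nramp1 was 2.6-fold higher. CRSH2 was 1.99-fold higher. PIN5 (PIN9), an auxin efflux carrier gene, was 30.4-fold lower (46.2 against 2018.4), and the TP309 array and the 4 overexpression lines stood at 38.9 to 47.5. BURP2 was 2.97-fold lower in sik2. Further named genes were higher by smaller log2 differences, among them the kinase gene CIPK10 (0.73), the dehydrin gene RAB16B (0.7), PXG (0.66), BGLU13 (0.63), the calmodulin-like gene CML11 (0.61), MAN1 (0.57) and GER1 (0.57). Lower were CYP71Z7 (−0.81), the vacuolar iron transporter gene VIT1.2 (−0.81), CAD8A (−0.8), PCF8 (−0.75), CDKE-1 (−0.74), CPDK2 (−0.74), CBF3 (−0.72), LAC20 (−0.68), PRXIIE-2 (−0.63) and DRB1 (−0.62). In all, 127 probe sets were at least 2-fold apart, 42 higher and 85 lower in sik2, of which 36 have a gene and 7 a named gene. Between the 2 full-length lines 112 probe sets were as far apart. Of the genes named as higher, all but CRSH2, RAB16B and PXG had their lowest signal of the 7 arrays in Nip. Nramp1 stood at 159.8 in Nip and 413.9 to 1183.7 in the other arrays, and CIPK10 at 167.3 and 290.2 to 431.8. Of the genes named as lower, only PIN5, VIT1.2, CAD8A and DRB1 had their highest signal in Nip. With 1 Nip array, its own deviation and an effect of the mutation cannot be told apart for such genes. JAZ2 was also high in 1 of the 2 lines of each construct, at 772 and 28.2 in the full-length lines and 730 and 32.6 in the truncated lines.

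Set against 10000 random lists of the same size matched on mean expression, LEA proteins and dehydrins had the median of highest percentile in sik2 over Nip, at 0.4 on the log2 scale (percentile 100; the middle 95% of random lists lay between −0.14 and 0.09). RAB16B stood at 0.7, PM1 at 0.55, RAB21 at 0.54 and LEA19 at 0.43. The random lists draw genes independently, whereas this list had an estimated correlation of 0.777 in the overexpression and TP309 arrays. RAB16B also stood at −0.54 and 0.89 in the 2 full-length lines over TP309. Root markers had a median of −0.22 (percentile 0.1), although NAS1 and NAS2 on that list were higher. Iron and zinc genes had a median of −0.11 (percentile 0.72), with NAS1, NAS2 and Nramp1 again above 0. Secreted peroxidases and laccases had −0.2 (percentile 0.68) and diterpenoid genes −0.17 (percentile 4.11). Cell wall growth genes had 0.06 (percentile 99.1), clock genes 0.1 (percentile 98.18), chitinases and PBZ1 0.01 (percentile 69.88) and small heat shock proteins −0.03 (percentile 32.07). The other lists lay between the percentiles 5.7 and 97.03. The pathogenesis-related list written before the annotation was seen, most of whose kept genes were matched too widely, had a median of 0.14 (percentile 99.81). These percentiles describe this pair of arrays. In a check on the measured differences of this same pair, 7 of 100 random lists of 20 genes fell outside the middle 95%.

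Whether loss and gain of OsSIK2 move genes in opposite directions was asked by setting the full-length comparison beside sik2 over Nip, which share no array. Across all kept probe sets the correlation was 0.055, with 0.211 for full-length line 1 and −0.1 for line 2. For the truncated lines it was 0.217 (0.054 for line 1 and 0.287 for line 2). Higher in the full-length lines and lower in sik2 were 6 probe sets (0.134 for independent lists), and none was lower in the lines and higher in sik2. The 6 were 2 probe sets of LOC4351887 (log2 4.1 and −1.22; 3.84 and −1.12), LOC4352852 (2.56 and −1.95), LOC4325422 (2.37 and −1.33) and 2 probe sets without a gene (1.86 and −1.15; 1.61 and −1.05). These were named after their values were seen. The 2 probe sets of LOC4351887 also differed between the controls, at 63.1 and 109.1 in TP309 and 2276 and 2936.3 in Nip. The full-length lines, at 1303.4 to 1980.7, lay nearer to Nip. This gene thus also varied between unaltered plants, and its opposite directions cannot be put down to OsSIK2. Higher in both were 9 probe sets (0.066 for independent lists), and lower in both was 1 (0.009). Of the truncated lines' 2-fold probe sets, 6 were also higher and 2 also lower in sik2 (0.035 and 0.122 for independent lists), and 1 was lower in the lines and higher in sik2. The numbers for independent lists take every probe set as equally likely to be 2-fold apart. Some probe sets may vary between any arrays, as 112 were 2-fold apart between the 2 full-length lines. No simulation was run for the overlaps with sik2, so an excess over these numbers was not tested.

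At 5 probe sets all 5 altered arrays were at least 2-fold above their own control, and at none were all 5 below. They were LOC4340325 (sik2 810.6 against 26.4 in Nip), both probe sets of LOC4331398 (sik2 2350.5 against 45.8, and 1816.6 against 10.7) and 2 probe sets without a gene (sik2 1026.7 against 30.1, and 741.7 against 44.5). These, too, were named after their values were seen. In the overexpression lines the last of these ranged from 620.1 to 3118.2 against 93.8 in TP309, and it did not pass the test in either comparison.

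**Figure D3:**
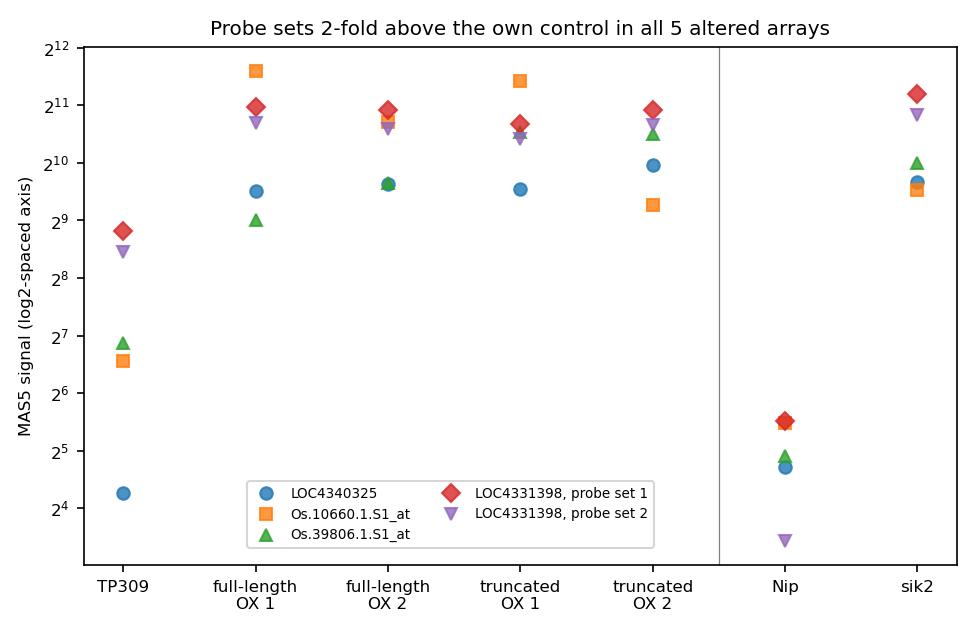
MAS5 signal (vertical axis, log2-spaced) of the 5 probe sets that were at least 2-fold above the own control in all 5 altered arrays, 1 point per array. From left to right the arrays are TP309, the full-length lines, the truncated lines, Nip and sik2. LOC4340325 stands at 730.9 to 1003.5 in the altered arrays, 19.2 in TP309 and 26.4 in Nip.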

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

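Tests chosen only after the result was seen were the clock genes, the RNA quality ratios, the scaling of the truncated difference, and the setting aside of 3 pairs of arrays. The first pattern drew attention because the effects of the truncated and full-length lines, each against TP309, differed at 55 probe sets in limma's test of the difference, 53 of them lower in the truncated lines (1246 of 1775 without truncated line 1, 367 of 621 without line 2). Array scaling as the whole cause is argued against by quantile normalization, after which 43 were still lower and past the test. A smaller share of dividing cells in the sampled shoots is argued against by the cell division list, as far as that list tracks such cells, which was not tested. Its 27 genes had a median log2 difference of −0.01 and a lower quartile of −0.1. Over TP309 the median was −0.07 in the truncated lines (20 genes lower) and −0.04 in the full-length lines (17 genes lower). RNA quality stays open: both truncated arrays lay below TP309, sik2 and Nip at 46 of the 53, and line 2 lay below TP309 at 50 with nearly the same ratios (GAPDH 2.99 and 2.91, actin 10.34 and 10.39), but this is 1 array of each, line 1 had a GAPDH ratio of 3.31, and Nip, with the highest GAPDH ratio (3.67), had the lowest actin ratio (6.75). A small shift in the time of harvest (CCA1 at −0.51, PCL1 at 0.49), the construct itself and differences between independently transformed lines also stay open and were not tested, and the same 53 probe sets had a median log2 difference of 0.07 in sik2 over Nip.

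A second pattern was the group of 5 probe sets higher in all 5 altered arrays than in their own control, the mutant included. Scaling is argued against by the array medians of 56.6 to 63.5, which are too close to give log2 differences of 1.82 or more. After quantile normalization 5 of the 5 were still 2-fold higher, but with such close medians that step could hardly give another outcome. A large shift in the time of harvest is argued against by clock genes, whose median absolute difference from the own control was at most 0.15 on the log2 scale. The largest single differences were those of CCA1 (0.4 and 0.37) and PRR1 (−0.49 and −0.48) in the full-length lines. They were followed by PCL1 in the truncated lines (0.46 and 0.3), so a small shift stays open. Array noise stays open, as the bound set beforehand, that of the 21 pairs of arrays the 2 controls have the most probe sets 2-fold apart from all other arrays, could hardly be met whatever the noise: 3 pairs had at least the controls' 5, among them sik2 and Nip, which share a background (119), and the truncated lines (15). Without the pair of sik2 and Nip and the pairs of lines of the same construct, the highest number among the 18 pairs left, apart from that of the controls, was 2, but some of these pairs share the TP309 background, and what all altered plants share, such as passage through tissue culture, may still be a source and was not tested.

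Another pattern was the higher level of the chitinase and PBZ1 list in both kinds of overexpression line, a list call that was lost with an estimated correlation (camera adjusted p = 0.92 in full-length and 0.819 in truncated lines). No member passed the test over all probe sets, and PBZ1 was not higher in truncated line 1 (−0.02). A TP309 array that is low for these genes may account for part of it, since the list's median was −0.22 in TP309 over Nip on the log2 scale, against a change of 0.51 in the truncated lines and 0.26 in the full-length lines. This lies between the bounds set beforehand for and against that explanation, which used the change in the truncated lines. However, the list's median was 0.28 in truncated line 1 and 0.74 in line 2, and with line 1 alone the bound for a low TP309 array would be met. It would also be met if the same rule were set on the full-length change of 0.26. A difference between the cultivars could give the same −0.22. With 1 TP309 array, its own deviation and an effect of the construct cannot be told apart for this list.

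Signals also appeared among 64 probe sets for reporter and marker sequences, of which 5 were bright enough to be among the kept probe sets. Of those that were not kept and so entered no comparison, 2 were at least 10-fold above both controls in some array. The first stood at 8540.5 in full-length line 1 and at 11.5 to 39.4 in the other arrays. The second stood at 1892.8 in truncated line 2, 61.1 in truncated line 1 and 20.7 to 29.5 elsewhere.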

How the results depend on the processing

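All alternatives were planned before the data were examined. No paired analysis was possible because every array is labelled as a first replicate of its own line and the line numbers were given in accession order. The probe sets past the test against TP309 in full-length lines (4) numbered 2 with quantile normalization (1 higher, 1 lower), 22 with no filter on dim probe sets (9 higher, 13 lower), 2 with a stricter filter on dim probe sets, 2 without the intensity trend, 322 with only the groups compared, 1 with Nip as a second control array and 0 to 323 with a line left out. In truncated lines (13) they numbered 33 with no filter, 0 with only the groups compared (limma; 925 at an unadjusted p under 0.05), 6 with Nip added and 0 to 849 with a line left out (262 higher and 587 lower without truncated line 1, 170 and 124 without line 2). Between truncated and full-length lines (55) they numbered 110 with no filter, 15 with a stricter filter, 22 with Nip added and 0 to 1775 with a line left out (529 higher and 1246 lower without truncated line 1, 254 and 367 without line 2, against 2 and 53). The 0s came without either full-length line (808 to 2873 at an unadjusted p under 0.05), and without a truncated line all 4, 13 and 55 still passed among the larger numbers. Then limma estimated the same spread for all probe sets of like brightness, and a lone line was assumed to vary like the others. All 4, 13 and 55 kept their sign in every such fit. With median centring 74 passed between truncated and full-length lines (7 higher, 67 lower). The 2-fold counts were 25, 30 and 53 with a stricter filter and 16, 25 and 25 at 3-fold for full-length lines (48), truncated lines (65) and sik2 (127). In the same order they were 59, 93 and 177 with no pseudocount and 34, 48 and 93 with a doubled one. With Nip in place of TP309 they were 225 and 287, and with a line left out 129 to 135 and 126 to 257 (74 higher, 52 lower; 79 higher, 178 lower), since only 1 line then has to pass. The overlap of full-length and truncated lines (14) was 25 with no filter (12 higher, 13 lower), 8 with a stricter filter, 6 at 3-fold and 18 to 22 with a line left out. The 7 list calls became 0 with an estimated correlation. The correlation of full-length lines and sik2 lay between 0.029 and 0.139, and between −0.1 and 0.211 with a line left out. Single named genes were followed only under quantile normalization and with no pseudocount. BZIP06 was no longer past the threshold after the former (−1.49), JAZ2 moved to 7.18 with the latter, and none changed sign under either. Except where the filter or the number of lines sets the count, the cause was not tested. Alternatives for OsSIK2 were not run. Dim signals limit the fold changes of probe sets near the pseudocount.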

Other observations

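The test on the cultivars was written after part of the values had been seen. The 2 control cultivars differed at least 8-fold at 53 probe sets, 27 higher in Nip and 26 in TP309. The sik2 array lay nearer to Nip at 50 of the 53, in keeping with a shared Nip background, and the 4 overexpression lines lay nearer to TP309 at 50 to 52. Both probe sets of LOC4351887 were among the exceptions in the full-length lines. The 3 exceptions in sik2 were PIN5, LOC4331398 and a probe set without a gene, where Nip stood at 309.4 and the other arrays at 2795.3 to 4987.4. Named genes far apart between the cultivars, picked after their values were seen, were the zinc finger gene OsC3H40 (29.9 in TP309, 1505 in Nip and 1525.4 in sik2), the methyltransferase gene ASMT1 (26.8, 782.7 and 513.2) and the triosephosphate isomerase gene Rictpi2 (190.2, 708.7 and 664.5).

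Lines of the same construct also differed from each other at named genes, picked after their values were seen. Truncated lines 1 and 2 stood at 712.1 and 129.4 for the jasmonate repressor gene JAZ13, at 1634.7 and 431.6 for the isocitrate lyase gene ICL, and at 2230 and 611.5 for BURP16. Of the 187 probe sets 2-fold apart between the truncated lines, 156 were higher in line 1 and 31 in line 2. Between the full-length lines, 46 were higher in line 1 and 66 in line 2.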
